A study of Zea mays with 8 samples.

How the data were processed

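Messenger RNA was sequenced from 8 maize leaf libraries, 4 treated with SLB and 4 with a Tween 20 control, all sampled at 24 h. Libraries were made with a stranded Illumina kit from 1.3 µg of total RNA, per the labels' protocols. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the number of mapped fragments), with 44135 maize gene identifiers and 1 column per library. Reads were trimmed with Trimmomatic 0.32 and the genome build was B73 RefGen_v4, per the submitters' processing notes. The aligner, the quantifier, the annotation version and any further scaling between libraries are not given in the sources used here. Columns were assigned to libraries through the deposited list of column names, and 0 columns of per-sample values were left unused.

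FPKM divide by the mapped fragments of a library, so when a few genes take a large share of the fragments, all other genes are pressed down in that library. The sequencing depth is unknown, and FPKM carry no interval for counting error. Low values were examined for a common step that would reveal the depth. Over the 28 pairs of libraries, the fullest bin of log2 ratios between low values (0.05 to 0.4 FPKM, bins of 0.02) held 1.15% to 3.28% of genes, so no single step was recovered. An exact 0 may be a failed estimate: 36 values of 0 stood in 1 control library where the other 3 controls had at least 10 FPKM, against 2 such values in the SLB libraries. Genes are therefore described as listed at 0. No pair of libraries was a duplicate, since at most 0.0352% of genes above 1 FPKM had equal values in any pair.

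The identifiers could not be turned into gene names. The reference gene table, of assembly Zm-B73-REFERENCE-NAM-5.0, has 49888 entries and matched 0 of the identifiers, so no symbol, product or coordinate is given. For the same reason the 28 gene lists fixed before the data were examined (terpenoid, hormone, defence, photosynthesis, ribosome and cell type lists among them) had 0 members and were not tested, and checks on gene length or GC content were void.

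Genes with at least 1 FPKM in at least 4 of the 8 libraries were tested, whatever the group. This kept 19407 genes and left out 24728. Values were taken to log2(FPKM + 1) and compared with limma 3.58.1 in R 4.3.3 (linear model on group, empirical Bayes with a trend on mean expression, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. The design, these settings and the alternatives were chosen before the data were examined, except for the rescalings named in the closing section as added later. Library-level measures were compared with a two-sided exact permutation test over all assignments of 8 libraries, whose smallest p is 0.0286, and adjusted over the 8 measures. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 was used for these.

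The rule for naming genes ranked those past the threshold, with no overlap between the groups' libraries, by fold change and required a name. As no identifier had one, that condition was dropped after the data were seen and only the first 2 in each direction are given. On simulated values for the SLB against control comparison, with 19407 genes at their observed means and spreads and 200 genes changed, limma recovered 60% of genes changed 2-fold and 91% of those changed 4-fold, and 1.95% of its calls were false. The simulation had no difference in scale between the groups, and in the data 80.6% of tested genes were called. These rates therefore check the method and do not carry over to the real comparison.

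Alternatives were another pseudocount (0.1 or 0.5), no filter or a filter at 5 FPKM, median-ratio scaling, quantile normalization, other variance models, the replicate number as a block, and leaving out each library. Both groups carry replicate numbers 1 to 4. Nothing in the labels says that a number marks a shared batch or day, so they were not treated as pairs. The labels do not say whether libraries came from separate plants, so p-values measure the spread between these libraries, which may be technical.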

Results

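The transcriptome of maize (Zea mays, cultivar Golden Queen) was profiled in the emerging leaf of young plants, 24 h after treatment. Plants were 14 d old, and the sampled leaf was leaf 4, not yet fully expanded. Of the 8 libraries, 4 came from leaves given a spore suspension labelled SLB and 4 from leaves given 0.1% Tween 20 in water. SLB stands in the published study for southern leaf blight, a foliar disease caused by the fungus Cochliobolus heterostrophus. The series title places the comparison in a study of maize diterpenoid defences, and the comparison asks which transcripts differ between infected and mock-treated leaves. Values were FPKM as deposited, in 44135 genes, of which 13397 were listed at 0 in all 8 libraries. The summed FPKM was 728937 ± 19929 (SD, n = 4) in SLB libraries and 1770918 ± 289130 (SD, n = 4) in controls. Genes are given by their B73 RefGen_v4 identifiers, without names or positions.

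The genes most abundant in the control leaf were lower in SLB libraries. The 50 genes with the highest mean FPKM in controls held 53.1% ± 3.52 (SD, n = 4) of the summed FPKM there and 5.49% ± 1.29 (SD, n = 4) in SLB libraries. All 50 of these genes fell past the threshold in limma, 45 of them by at least 8-fold. The ratio of control mean to SLB mean ranged from 3.5 to 184 with a median of 32.1, and 45 of the 50 also fell under each of the 5 rescalings tried. Of the 50 genes most abundant in SLB libraries, 33 rose, 12 fell and 5 did not pass the threshold, and 10 were also among the control 50. Under the deposited scale and all 5 rescalings, 28 of them rose and 5 fell. Each set was picked for its level in one group, which by itself pushes the control 50 towards falling and the SLB 50 towards rising, so their shares and counts describe the change, are not compared and do not test it. Of the 33 that rose, 23 rose by at least 8-fold. The 50 genes most abundant in SLB libraries held 21.3% ± 2.58 (SD, n = 4) of the summed FPKM in SLB libraries and 20.6% ± 1.21 (SD, n = 4) in controls. These shares are of each library's own total, which was higher in controls. They include the 10 genes shared with the control 50, all of which fell, so a like share does not mean that the genes were unchanged.

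**Figure D1:**
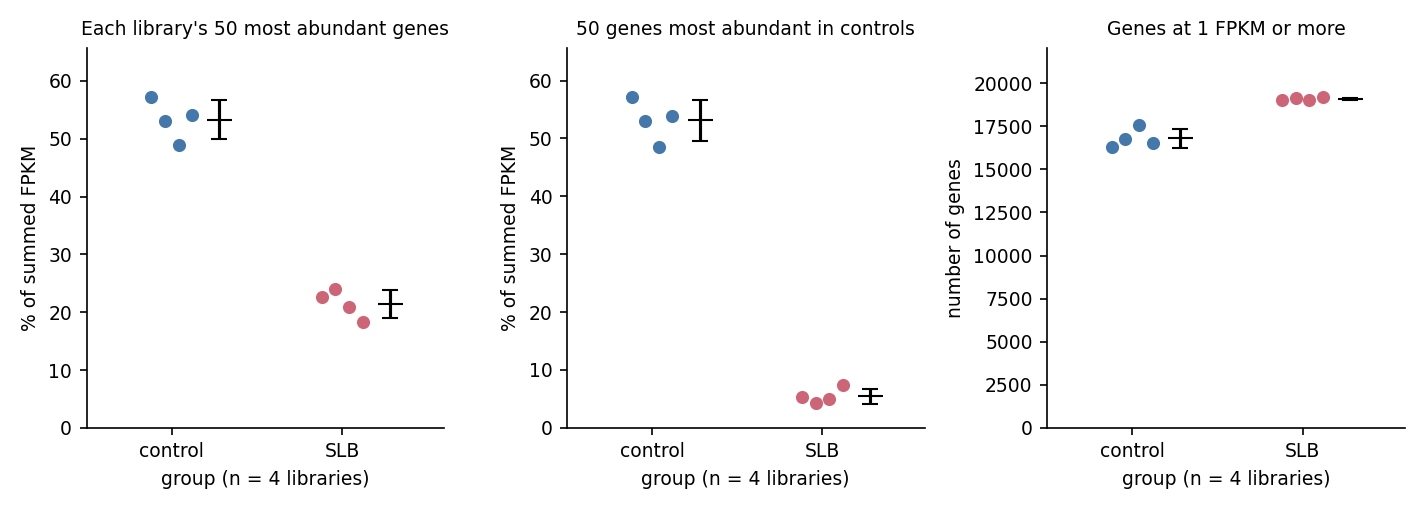
Share of summed FPKM (%) held by each library's own 50 most abundant genes (left) and by the 50 genes most abundant in controls (middle), and number of genes at 1 FPKM or more (right); points are libraries, bars are mean ± SD, n = 4 per group. The control 50 hold 53.1% on average in controls and 5.49% in SLB libraries, and no SLB library overlaps a control in any panel.

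Expression was spread over more genes in the SLB leaves. Each library's own 50 most abundant genes held 21.4% ± 2.43 (SD, n = 4) of its summed FPKM after SLB treatment and 53.3% ± 3.42 (SD, n = 4) in controls. The single highest gene reached 13890 ± 3235 FPKM (SD, n = 4) in SLB libraries and 93515 ± 28371 FPKM (SD, n = 4) in controls. The number of genes at 1 FPKM or more was 19089 ± 79.8 (SD, n = 4) in SLB libraries and 16794 ± 551 (SD, n = 4) in controls. After median-ratio scaling the same numbers were 18123 ± 66.5 and 17661 ± 211 (SD, n = 4). For each of these comparisons the 4 SLB libraries lay apart from the 4 controls, which gives the smallest p the exact permutation test allows, 0.0286 (two-sided, adjusted p = 0.0327 over 8 measures).

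Most expressed genes differed between the groups. Of 19407 tested genes, 15636 (80.6%) passed an adjusted p of 0.05 in limma, 10863 rising and 4773 falling with SLB treatment. These are differences between the groups, and any handling that differed between them cannot be told apart from the treatment. A change of at least 2-fold was called for 11387 genes, of which 7917 rose and 3470 fell. At 8-fold or more, 1060 genes rose and 849 fell, and at 64-fold or more, 109 rose and 19 fell. These splits turned with the scaling: at 8-fold or more, 617 rose and 1454 fell after median-ratio scaling, 753 and 1086 after quantile normalization, and 2951 and 315 with equal totals. At 64-fold or more, median-ratio scaling gave 69 rising and 72 falling. The counts also moved with the pseudocount. With 0.1, 2442 rose and 1318 fell at 8-fold or more, and 388 rose and 88 fell at 64-fold or more. With 0.5, 1491 rose and 1050 fell at 8-fold or more, and 158 rose and 31 fell at 64-fold or more. The genes that rose at least 8-fold held 24.5% ± 3.74 (SD, n = 4) of summed FPKM in SLB libraries and 0.287% ± 0.0622 (SD, n = 4) in controls. Those that fell at least 8-fold held 6.34% ± 1.9 (SD, n = 4) and 67.5% ± 3.67 (SD, n = 4). Both groups were chosen for their change, so these shares describe its weight in the transcriptome and do not test it. With FPKM as deposited, in 75.5% of tested genes the 4 SLB libraries did not overlap the 4 controls, where chance gives 2.86%. SLB libraries lay higher in 10337 of these genes and lower in 4314. A common factor between the groups can separate genes by itself, and this share was not computed under another scaling.

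The balance between rising and falling genes depended on how libraries were scaled. With FPKM as deposited, 69.5% of called genes rose and the median log2 fold change of all tested genes was 0.69. Median-ratio scaling moved that median to 0.02, and 7764 genes rose and 7456 fell, so that 51% of called genes rose. Setting all libraries to equal totals moved it to 1.65, and 14467 genes rose and 2340 fell, or 86.1% rising. Under the deposited scale and all 5 rescalings, 7187 genes rose and 2331 fell past the threshold, 4011 and 1761 of them by at least 2-fold, and 592 and 303 by at least 8-fold. Each shared count is capped by the scaling least favourable to its direction, 7764 rising under median-ratio scaling and 2340 falling with equal totals. The ratio of shared rising to falling genes therefore depends on the rescalings chosen and does not test the balance. Libraries separated by group first: the first principal component held 89.7% of the variance with all SLB libraries on one side. Spearman correlations across tested genes were 0.957 to 0.975 between SLB libraries, 0.938 to 0.947 between controls and 0.481 to 0.658 between the groups.

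**Figure D2:**
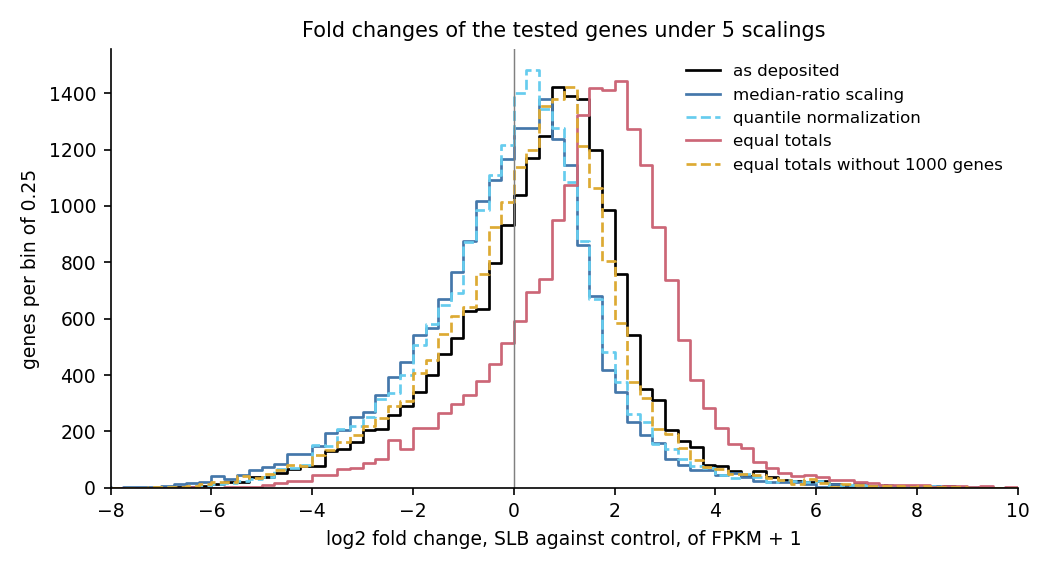
Number of tested genes (y axis, per bin of 0.25) by log2 fold change of FPKM + 1, SLB against control (x axis), for the deposited values and 4 rescalings. The median lies at 0.69 as deposited, 0.02 after median-ratio scaling and 1.65 with equal totals, and long tails on both sides remain under each.

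With FPKM as deposited, the direction of change followed abundance. Among the 132 genes with a mean of at least 1000 FPKM over the 8 libraries, 106 fell and 20 rose, with a median log2 fold change of -4.01 (quartiles -4.92 and -1.50). In the class of 100 to 1000 FPKM, 680 of 1263 genes fell and 439 rose. Between 10 and 100 FPKM, 4118 of 7653 genes rose and 2235 fell, and between 1 and 10 FPKM, 5940 of 9941 rose and 1722 fell. The 106 falling genes of the highest class included 83 that fell at least 8-fold, and 89 genes of that class fell under every rescaling, against 16 that rose under every one. In the classes of 1 to 10 and 10 to 100 FPKM, 3946 and 2814 genes rose under every rescaling, against 778 and 998 that fell. Between 100 and 1000 FPKM, 275 rose and 445 fell under every one. Such shared counts are capped by the scaling least favourable to each direction, so their split within a class depends on the rescalings chosen. The median log2 fold change was 0.82 at 1 to 10 FPKM and 0.59 at 10 to 100 FPKM. Over all tested genes it was 0.69, which median-ratio scaling moved to 0.02. Whether most called genes of these lower classes rose under that scaling alone was not computed. Ranking by mean log2(FPKM + 1) in place of mean FPKM also gave 106 falling genes among the top 132, with 14 rising. A mean FPKM is weighted towards the group in which a gene is higher, and the controls have the higher totals.

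**Figure D3:**
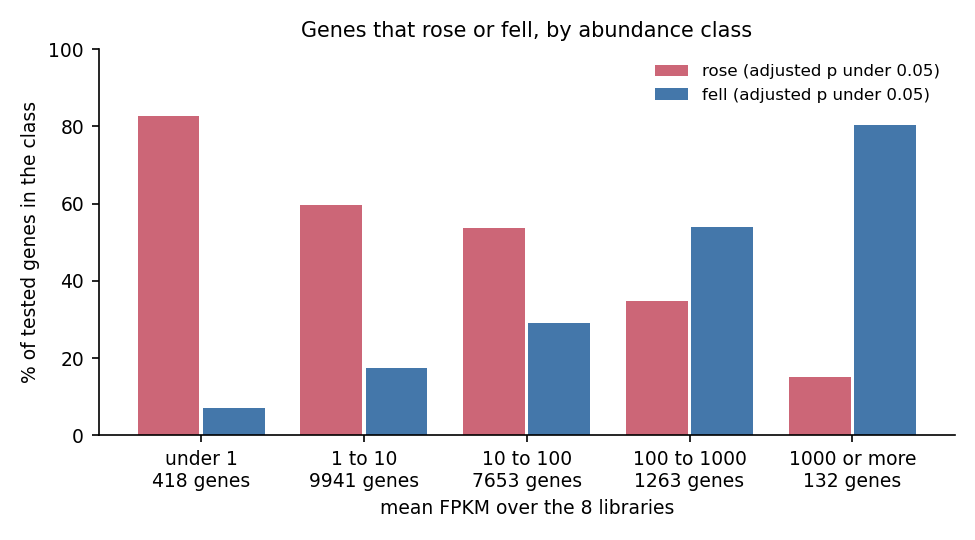
Percentage of tested genes in each class of mean FPKM over the 8 libraries (x axis) that rose (red) or fell (blue) with SLB treatment at an adjusted p under 0.05 in limma. Falling genes make up 106 of the 132 genes at 1000 FPKM or more and 1722 of the 9941 genes at 1 to 10 FPKM; with a minimum of 1 FPKM in 4 libraries, genes under a mean of 1 are mostly expressed in one group.

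Several genes were listed at 0 in one group and expressed in the other. At least 1 FPKM in all 4 SLB libraries and 0 in all 4 controls was found for 329 genes, and the opposite for 22 genes. With a minimum of 10 FPKM in place of 1, the numbers were 89 and 3. A value of 0 in this table may also be a failed estimate, and the numbers at 1 FPKM move with the scaling of the libraries. Single values of 0 beside at least 10 FPKM in the other 3 replicates numbered 36 in controls and 2 in SLB libraries. Failed estimates may thus weigh more on the genes listed at 0 in controls, and the difference between 329 and 22 cannot be told apart from them.

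Of the genes that rose, Zm00001d018738 ranked first, with 6718 ± 2202 FPKM (SD, n = 4) in SLB libraries, 7.69 FPKM in control replicate 1 and 0 in the other control libraries. The second, Zm00001d036539, was at 3805 ± 758 FPKM (SD, n = 4) after SLB treatment and 0.831 ± 0.92 FPKM (SD, n = 4) in controls, a log2 fold change of 11.12 (SE 0.30, limma adjusted p = 8e-09). Of the genes that fell, Zm00001d014718 ranked first and was listed at 0 in all 4 SLB libraries, against 691, 554, 409 and 613 FPKM in control replicates 1 to 4. The second, Zm00001d009589, was at 16921 ± 5066 FPKM (SD, n = 4) in controls and 92.1 ± 35.1 FPKM (SD, n = 4) in SLB libraries, a log2 fold change of -7.54 (SE 0.31, limma adjusted p = 7.11e-08). In each of these genes every SLB library lay on one side of every control, as the rule for naming genes required. The size of both folds moved with the settings, and the ranks hold for the deposited values with a pseudocount of 1. After quantile normalization, more genes than Zm00001d014718 alone fell further than Zm00001d009589. For Zm00001d036539 the log2 fold change was 12.46 with a pseudocount of 0.1, 10.52 after median-ratio scaling and 12.02 after quantile normalization. For Zm00001d009589 it was -8.37 after median-ratio scaling, -6.12 after quantile normalization and -6.28 with equal totals. No fold is given for the first of each pair, because of its values of 0.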

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

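The tests that set libraries to equal totals without the most abundant genes were chosen after the deposited values had been seen, and the one without 1000 genes after the one without 100 had been run.

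A single sample stood far from the other 3 of its group in 2 of 25 groups of library-level or gene-level values checked, where chance gives about 1 in 20. Control replicate 3 had 24629 genes above 0 FPKM, while the other controls had 23052 to 23251. Control replicate 1 had 7.69 FPKM of Zm00001d018738, while the other controls were listed at 0. With those tied at 0, any value above 0 would be flagged, so this flag carries no weight. The rate of 1 in 20 is for untied and independent values, and the values checked are not independent.

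In limma, no split of the 8 libraries other than the real one called any gene after adjustment, and the other splits gave at most 1384 genes at an unadjusted p under 0.05, against 15806 for the real one. The real split gave 15636 genes at an adjusted p of 0.05, the highest of the other splits gave 0, and 1 of the 35 splits, the real one, reached the real count. For genes changed at least 2-fold, the real split gave 11387, the highest other gave 0, and again 1 of the 35 splits reached the real count. For both, 1 of 35 is the smallest share these splits allow, so it argues against chance assignment of libraries only down to that floor. Every other split mixes SLB and control libraries, which adds the group difference to its spread, so the size of the gap adds little.

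More genes rose than fell with the deposited values (69.5% of called genes rose), and very abundant control genes pressing down the rest are a candidate explanation. With equal totals the share rising was 86.1%, and with the 100 or 1000 most abundant genes taken out of the totals it was 73% and 64.2%, the first above the deposited share and the second below it. Both shares stayed above 60%, the bound against those genes as the whole cause. That bound was set before each outcome was seen, but after the deposited values had been. For 1000 genes the share was 63.4% to 65.5%, leaving out each library in turn. The share fell from that with equal totals as more genes were taken out, which such a press would also give. Summed FPKM are also not fragment counts, so the test does not decide on that explanation. With FPKM as deposited, genes near the detection limit alone are argued against by the 60.2% rising among called genes with a mean of at least 10 FPKM. By class that share was 64.8% at 10 to 100 FPKM, 39.2% at 100 to 1000 and 15.9% at 1000 or more. It was not computed under another scaling, so it does not decide on that explanation beyond the deposited scale. Whether the treatment raised more genes than it lowered, beyond a common factor between the groups, cannot be told apart from the scaling. Of genes changed at least 8-fold, 29.8% rose after median-ratio scaling, which centres the median by construction, and 40.9% after quantile normalization. That share was 90.4% with equal totals, 62.5% without the 100 and 47.1% without the 1000 most abundant genes in the totals. The authors' normalization and broader changes in composition also stay open.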

How the results depend on the processing

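The rescalings to equal totals, with all genes or without the 100 or 1000 most abundant, were added after the data were seen; all others were chosen beforehand. The 6 counts of genes were computed under 21 settings, and 119 of 126 values stayed within 1.5 times the reported count. The 7 others all came from scaling between libraries. Under median-ratio scaling 7456 genes fell, 4586 rose at least 2-fold and 5311 fell at least 2-fold. With quantile normalization 4834 rose at least 2-fold. With equal totals 2340 genes fell, 12917 rose at least 2-fold and 1766 fell at least 2-fold. These shifts follow from the construction of the settings, which move all genes of a library by 1 factor or to 1 distribution. With FPKM as deposited and with median-ratio scaling, 248 genes were called in opposite directions, against 154 for quantile normalization and 478 for equal totals. Leaving out 1 library gave 15142 to 15780 called genes and 11106 to 11821 changed at least 2-fold. The counts at 8-fold and 64-fold or more are not among the 6 counts above, and they also moved with the pseudocount. The 4 named identifiers kept their direction and stayed past the threshold in all 84 values, though their fold changes moved with the scaling. Same-numbered libraries correlated at 0.0485, 0.0152, 0.126 and 0.112 in their deviations from the group means. For numbers 3 and 4, the SLB and control library each correlated best with the other, which was not so for numbers 1 and 2. The values therefore do not settle whether the numbers pair the libraries. With the number as a replicate block, 15617 genes were called. The gene list alternatives were not run, since no list had members. Depth is unknown, so calls among low genes carry an error that the FPKM do not show.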

Other observations

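The first test of neighbouring identifiers was chosen after a first look at the data; the ratios of replicate spread carry a correction added after their first values were seen, and the other tests were set before their outcome was seen.

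Genes with consecutive identifier numbers changed alike more often than random pairs. Identifier numbers are taken here to follow gene order along the assembly, which was not checked. Over 8395 such pairs the log2 fold changes correlated at r = 0.121 across genes, above the highest of 1000 random orders (0.0342), and the correlation was 0.0575 at a distance of 2, 0.0279 at 5 and 0.00819 at 50. Both members rose at least 8-fold in 91 pairs, where random orders gave 24.8 on average and 44 at most. Both members fell at least 8-fold in 28 pairs, where random orders gave 16.1 on average and 4 of 1000 gave as many. Runs of 3 or more consecutive genes that rose at least 8-fold numbered 11, against at most 3 in 200 random orders, and 1 run of genes fell, within the range of random orders.

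The likeness of neighbours was not carried by one stretch of identifiers: over 10 equal stretches the lowest correlation was 0.0505 and the highest 0.158, and without any 1 stretch the pooled value was 0.117 to 0.129. Shared regulation of neighbouring genes and fragments assigned to more than 1 of several tandem copies may each give such a pattern. The table holds no sequence or read counts that would separate them, and genes are not independent replicates.

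Control replicates appeared to spread more than SLB replicates, but the difference was not resolved. The median absolute deviation from the group mean was 0.175 ± 0.0551 (SD, n = 4) log2 units in controls and 0.132 ± 0.0229 (SD, n = 4) in SLB libraries (exact permutation test, two-sided p = 0.229). The ratio of median within-group SDs, corrected for the number of libraries, was 1.34 with deposited values and 1.39 after median-ratio scaling, which argues against scaling differences among controls. Among 1691 genes of at least 10 FPKM and little change, picked on deposited values, it was 1.19 with deposited values and 1.46 after median-ratio scaling. That scaling shifts the groups against each other, so these genes are not of little change on its scale. The ratio of 1.19 lies just under the bound of 1.2 set against lower expression in the controls, and 1.46 does not test it, so that explanation stays open. Leaving out control replicate 3 brought the ratio over all tested genes to 1.08, while leaving out any of the other controls gave 1.32 to 1.53. A single deviating control library is thus a candidate source. By library, the median absolute deviation was 0.202, 0.118, 0.239 and 0.143 in control replicates 1 to 4, so replicate 1 also stood high. Leaving out SLB replicates gave 1.25 to 1.55.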
